A study of Mus musculus with 2 samples.

How the data were processed

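The deposited files hold 1 table per library of UMI counts per gene and cell barcode, unnormalized; they hold whole numbers, and every gene listed has a UMI in at least 5 cells of its library. Per the labels' protocols, live CD45+ CD11b+ Ly6G- cells were sorted from tibialis anterior muscle 4 days after injection of 50 µl of 10 µM cardiotoxin, and 8000 cells of each genotype were loaded for 10x Chromium Single Cell 3' libraries. Per the submitters' processing notes, Cell Ranger 3.0.1, Seurat 3.0.2 and R 3.6.1 were used with the build mm10; their settings and any filter on cells are not given in the sources used here. The Wt library lists 13905 genes and the Gata3KO library lists 13755, of which 13289 are in both and were compared; 13161 of these matched a gene name of the GENCODE annotation of the same build, from which identifiers and coordinates were taken. The lowest number of genes per barcode was 399 in Wt and 501 in Gata3KO.

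Cells were kept with at least 500 UMIs, at least 200 genes and at most 10% of UMIs from mitochondrial genes. Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together without integration, on 2000 variable genes (scanpy 1.11.5), 30 principal components, a graph of 15 neighbours weighted by shared neighbours (scikit-learn 1.9.0) and Leiden clustering at resolution 0.6 (leidenalg 0.10.2, igraph 0.11.9). Each cluster took the class of the marker list, fixed before the data were examined, with the highest mean z-score. After the data were seen, a score under 0.15 left a cluster unnamed, as did leading cell-cycle genes with a mixed makeup. Cluster 4 joins cycling macrophages (32 Wt and 72 Gata3KO cells) with collagen-rich cells (34 and 22). The design fixed beforehand counted cycling cells among monocytes and macrophages; after the mixture was seen they were left out, and the macrophage part was added as an alternative. Doublets were scored with Scrublet per library, which called 0 of 990 Wt and 4 of 650 Gata3KO cells (0.615%); they were left in.

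UMIs of each class were summed per library and expressed as CPM (UMIs scaled to a common total). The log2 ratio Gata3KO over Wt has an exact conditional binomial interval, sums have exact Poisson intervals and shares exact Clopper-Pearson intervals, at the 95% level (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). With 1 library per group no test was made. Gene lists use members at 20 or more CPM in at least 1 library with 1 CPM added, and 10000 random lists matched on expression. To compare shares of cells with a UMI, each cell was thinned to 2000 UMIs. Where a count was 0, 3 counts served as the floor.

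The rule for named genes, fixed before the data were examined, took *Gata3* and *Cx3cr1*; in monocytes and macrophages the 12 largest log2 ratios each way among genes with at least 50 CPM in 1 library and 100 UMIs over both, passing over *Xist*, *Tsix*, Y-linked, haemoglobin, immunoglobulin and predicted genes; of each list up to the 2 highest and 2 lowest members; in clusters with at least 100 cells of each library the 4 largest each way at 100 CPM; and a fixed panel for shares. Genes that lead a cluster are named to describe it. A gene that the rule selects is not reported here.

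The ratio, ranking and list steps were tested on simulated libraries of 2897 genes for the Gata3KO and Wt comparison, with 200 genes changed by known folds. Counts were drawn from 1 pooled profile with counting error only, and the genes judged had at least 50 CPM. Differences between cells, clusters or animals were not simulated, so the check covers the calculation alone. All 67 genes changed 1.5-fold, all 67 changed 2-fold and all 66 changed 4-fold had an interval on the right side of 0, the intervals held the true value for 95.3% of genes, all 24 top-ranked genes were changed ones, and 4 of 200 lists of unchanged genes lay outside the central 95% of random lists.

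Alternatives planned before the data were examined were: every barcode; at least 1000 UMIs and at most 5% mitochondrial UMIs; called doublets left out; Leiden resolutions 0.3 and 1.2; a class per cell from marker scores; median-of-ratios scaling; totals without mitochondrial and ribosomal protein genes; every cell weighted alike; cells thinned to 2000 UMIs; all kept cells; cluster shares held equal; list filters of 0 and 100 CPM; 10 CPM added; and panel shares thinned to 1000 UMIs or not thinned. Added after seeing the data were a mitochondrial limit of 20%, the cycling macrophages included, the cells with the most UMIs left out (981 Wt and 635 Gata3KO cells stayed), and finer cluster shares held equal, from clusters with at least 5 cells of each library. Also after seeing the data, the lists for MHC class II, iron and haem, lysosome and repair were added to the main results followed through the alternatives. With shares held equal, each value was the mean of the log2 ratios within the clusters of the class. These ratios had 1 CPM added and were weighted by the cells of both libraries. Figures were drawn with matplotlib 3.10.9.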

Results

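Myeloid cells were profiled by droplet single-cell RNA sequencing 4 days after cardiotoxin, a membrane-lysing snake venom toxin that destroys muscle fibres, was injected into the tibialis anterior muscle of mice. Live cells that carried CD45 and CD11b and lacked the neutrophil marker Ly6G were sorted. There were 2 libraries, 1 from C57BL/6 mice (Wt) and 1 from mice in which Cre recombinase driven by the *Cx3cr1* gene deletes a floxed *Gata3* gene in monocytes, macrophages and other cells that express *Cx3cr1* (Gata3KO). The comparison asks how macrophages of regenerating muscle differ when the transcription factor Gata3 is deleted from them; the series title places it in a study of how the cytokine IL-33 rewires macrophage metabolism and the resolution of inflammation.

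The Wt table held 3290 cell barcodes and 15392330 UMIs (unique molecular identifiers, counted transcripts), with a median of 2616 UMIs per barcode. The Gata3KO table held 3434 barcodes and 19422237 UMIs, with a median of 3059. The median share of mitochondrial UMIs was 15.7% in Wt and 21.8% in Gata3KO, so the limit of 10% mitochondrial UMIs left 990 Wt cells (30.1% of barcodes) and 650 Gata3KO cells (18.9%). The kept Wt cells had a median of 5836 UMIs and the kept Gata3KO cells a median of 13716. With 1 library per genotype there was no test and no replicate check, as cells are not replicates. Intervals of single genes and of shares cover counting error only, at the 95% level. Intervals of medians over genes are 95% order-statistic intervals, which reflect the spread between genes and not counting error. Neither kind covers differences between animals. A difference between the libraries cannot be separated from a difference between the animals or preparations behind them. Transcripts of the Y chromosome were present in both libraries (*Ddx3y* at 38.9 CPM, UMIs scaled to a common total, in Wt and 42.2 in Gata3KO).

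*Gata3* itself was too rare in these cells to check the deletion. In the kept cells 4 *Gata3* UMIs were counted in Wt and 1 in Gata3KO (log2 ratio Gata3KO over Wt -2.22, exact interval -7.84 to 1.12), and over every deposited barcode there were 8 in each library. *Gata3* (ENSMUSG00000015619) lies on the minus strand of chromosome 2 at 9857078 to 9890034 in mm10, and tags from the 3' end of its transcript can also lie outside the floxed part. *Cx3cr1* (ENSMUSG00000052336, the fractalkine receptor, chromosome 9 at 119901616 to 120069879, minus strand), which drives the Cre line, was higher in the Gata3KO library. In monocytes and macrophages it stood at 268 CPM in Wt and 372 in Gata3KO (log2 ratio 0.47, interval 0.37 to 0.57), and in all kept cells at 226 and 360.

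Monocytes and macrophages were the largest named class in both libraries, and dendritic cells were the next. Joint clustering of the kept cells gave 9 clusters, numbered from 0 by size. Clusters 1, 2 and 3 formed the class of monocytes and macrophages. Cluster 1 was lipid-handling macrophage-like and led by *Gpnmb*, *Fabp5* and *Spp1*. Cluster 2 was led by interferon-induced genes such as *Ifit2* and *Gbp2* together with the monocyte genes *Ccr2* and *Plac8*. Cluster 3 was lipid-handling macrophage-like by its markers, but its leading genes were the inflammatory and stress genes *Cxcl2*, *Gdf15*, *Ier3*, *Tnf* and *Hmox1*. Clusters 5 and 8 were conventional dendritic cell 2-like (*Cd209a*), with early-response genes (*Nr4a2*, *Hspa1a*) leading cluster 8, and cluster 6 was mature dendritic cell-like (*Ccr7*, *Fscn1*). Cluster 7 carried muscle transcripts (*Acta1*, *Mylpf*, *Myog*).

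Of the kept cells, 41.7% in Wt (413 of 990, exact binomial interval 38.6 to 44.9%) and 60.9% in Gata3KO (396 of 650, 57.1 to 64.7%) were monocytes and macrophages, a difference of 19.2 percentage points. Dendritic cells took 17.6% in Wt (15.3 to 20.1%) and 8.46% in Gata3KO (6.44 to 10.9%), a difference of -9.11 points. The muscle-transcript cluster took 3.13% in Wt and 0.615% in Gata3KO, and unnamed cells took 37.6% and 30%. The unnamed cells were cluster 0, low in UMIs (median 2230) and holding 30.9% of Wt and 15.5% of Gata3KO cells, and cluster 4, led by cell-cycle genes and holding 6.67% and 14.5%. Both were left unnamed by limits set after seeing the data. Cluster 0 was led by *Gm42418*, *Gm26917*, *Slfn4*, *Lars2*, *AY036118* and *Malat1*. Its median mitochondrial share, 7.52%, was the highest of the clusters, and its cell type was not resolved. The sort and the mitochondrial limit chose the cells, and depth differed (median 8862 UMIs in Wt and 17227 in Gata3KO monocytes and macrophages). The differences for monocytes and macrophages and for unnamed cells turned with the limit, while that for dendritic cells kept its sign (-6.78 points): among all deposited barcodes, reclustered, monocytes and macrophages made up 66.7% in Wt and 26.7% in Gata3KO, while 17.4% and 66.4% stayed unnamed.

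**Figure D1:**
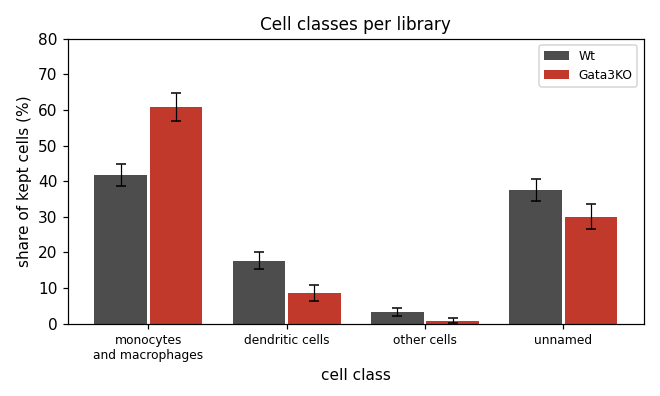
Share of kept cells (%, y axis) in each cell class (x axis) in the Wt and the Gata3KO library, with exact 95% binomial intervals that cover counting error only. Monocytes and macrophages took 41.7% of Wt and 60.9% of Gata3KO cells, and dendritic cells 17.6% and 8.46%.

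Within monocytes and macrophages, the Gata3KO library had lower levels of interferon-induced genes and higher levels of *Chil3*, *Arg1* and *Hmox1*. The class is made of different clusters in the 2 libraries: cluster 2 gave 231 of the 413 Wt cells and 33 of the 396 Gata3KO cells, cluster 1 gave 124 and 198, and cluster 3 gave 58 and 165. The class summed to 4479621 UMIs in Wt and 6807856 in Gata3KO. Of 3094 genes with at least 50 CPM in 1 library and at least 100 UMIs in all, those named are the 12 with the largest log2 ratio each way.

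The gene furthest higher in the Gata3KO library was *Chil3* (ENSMUSG00000040809, chromosome 3 at 106147554 to 106167564), which encodes the chitinase-like protein Ym1 of alternatively activated macrophages. *Chil3* is also on the fixed list of monocyte markers. It stood at 47.1 CPM in Wt and 352 in Gata3KO, 7.48-fold higher (log2 ratio 2.90, interval 2.70 to 3.11). *Arg1*, the arginase of the same state, had a log2 ratio of 2.65 (2.16 to 3.18) but a low level, 8.26 CPM in Wt and 51.9 in Gata3KO. *Hmox1* (ENSMUSG00000005413, chromosome 8 at 75093621 to 75100589), the haem-degrading enzyme, went from 120 in Wt to 679 in Gata3KO (log2 ratio 2.5, 2.37 to 2.63), and *Gclm*, which takes part in glutathione synthesis, had a log2 ratio of 1.87. The others higher in Gata3KO were *Gdpd3* (2.67), the scavenger protein gene *Cd5l* (2.08), *Ifi27* (1.89), the neutrophil chemokine gene *Cxcl1* (1.79), *Thbs1* (1.69), the growth factor genes *Gdf3* (1.61) and *Gdf15* (1.59), and the lipid droplet gene *Hilpda* (1.39). Holding shares equal averages the log2 ratios within clusters, whatever the level of the gene there. On that average *Arg1* turned lower in Gata3KO (-0.73), and so did *Hilpda* over finer clusters (-0.30). *Hmox1* stood at 0.81 over finer clusters and at 0.20 (-0.01 to 0.42) within cluster 1, against 2.88 within cluster 3. The genes that lead finer cluster 1 (29 Wt and 161 Gata3KO cells) include *Gdf15*, *Cxcl1*, *Hmox1*, *Arg1* and *Hilpda*. Holding its share equal thus conditions on these genes, so their smaller values cannot show that makeup is the cause. *Gclm* stood at 1.03 with finer cluster shares held equal and was level within cluster 1 (0.03, -0.36 to 0.43). In that setting, with 1 CPM added, *Cd5l* (1.43), *Thbs1* (1.15), *Cxcl1* (1.05), *Gdf3* (0.98), *Ifi27* (0.91) and *Gdf15* (0.86) were also smaller. *Chil3* (4.43) and *Gdpd3* (2.76) were larger. Of the *Arg1* UMIs, 352 of the 353 in the Gata3KO class came from cluster 3. In finer cluster 1, which lies mostly in cluster 3, *Arg1* was higher in Gata3KO (1.25 with 1 CPM added). It was lower in finer clusters 2 (-1.16), 4 (-2.59) and 7 (-1.86), which lie mostly in clusters 1 and 2. The turn with shares held equal thus rests on clusters that held almost none of the Gata3KO *Arg1* UMIs.

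Of the 12 genes named as lower in the Gata3KO library, *Gbp2*, *Ifi205*, *Ifit2* and *Ifit3b* are on the fixed interferon response list. *Serpina3g* (ENSMUSG00000041481, chromosome 12 at 104236245 to 104241939) was 23.8-fold lower in Gata3KO than in Wt (log2 ratio -4.57, interval -5.43 to -3.82), and *Cxcl9* (ENSMUSG00000029417, chromosome 5 at 92321347 to 92328079), a chemokine gene induced by interferon gamma, went from 182 CPM in Wt to 7.79 in Gata3KO (-4.54, -4.97 to -4.14). The T cell chemokine gene *Ccl5* had a log2 ratio of -4.27, the guanosine triphosphatase genes *Iigp1* and *Gbp2* had -3.97 and -3.61, and *Ifi205*, *Ifit2*, *Ifit3b* and *Isg20* had -3.43, -3.26, -3.04 and -2.99. *Ccl5* stood at 173 CPM in Wt, against 9799 CPM in the mature dendritic cell-like cluster 6. Whether dendritic cell RNA in the class brought its Wt level was not tested. *Plac8* (-3.11) and *Ifitm6* (-2.90), which mark monocytes, and *Slfn1* (-2.91) complete the set. The predicted gene *Gm47283* ranked among them (-2.97) and was passed over by the rule; *Ifi205* and *Ifit3b* have close paralogs, so their counts depend on how reads were assigned.

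**Figure D2:**
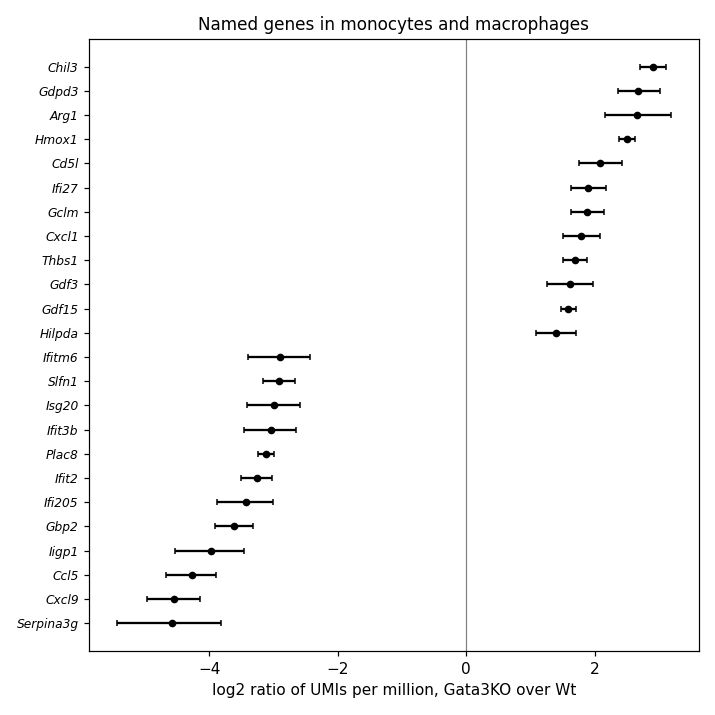
Log2 ratio of CPM, Gata3KO over Wt (x axis), of the 12 genes furthest each way (y axis) in monocytes and macrophages. Bars are exact 95% counting intervals; *Chil3* lies at 2.90 and *Serpina3g* at -4.57.

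The gene lists fixed before the data were examined are given as the median log2 ratio of their measured members and its percentile among 10000 random lists of the same size and expression, as a description of these libraries. The median of all 5884 measured genes was 0.04. On the interferon response list 29 of 29 measured members were lower in the Gata3KO library by over 1.5 times. The list median was -2.18 (95% interval of the median over genes -2.5 to -1.84, percentile 0). The smallest difference among the members was in *Oas1a* (-0.82), followed by *Ifi204* (-1.41). *Ifi27*, which is not on the list, was higher (1.89). Antigen presentation by MHC class II was also lower, in 8 of 8 members (median -1.56, percentile 0), with *H2-Ab1* at -1.83, *H2-Eb1* at -1.90 and *H2-DMa* at -0.86; the costimulatory gene *Cd86* differed least (-0.27) and turned to 0.0126 over every deposited barcode. With finer cluster shares held equal the MHC class II median was -0.58, and that of dendritic cell genes went from -1.50 to -0.25. Monocyte-enriched genes (median -0.82, 10 of 12 lower, percentile 0) and cholesterol synthesis genes (-0.62, 7 of 8 lower, percentile 0; *Pmvk* -1) were lower too. The interval of the cholesterol synthesis median included 0 (-1.03 to 0.04). The monocyte list turned to 0.12 with finer cluster shares held equal.

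Higher in the Gata3KO library were repair and growth factors (median 0.77, 11 of 14 higher, percentile 100; *Pdgfb* was lower at -0.71), iron and haem handling (0.62, 14 of 14 higher, percentile 100; *Tfrc*, the transferrin receptor, at 1.44 and *Trf* at 0.20), the hypoxia response (0.60, 8 of 10, percentile 100; *Bnip3l* 0.86), lysosome and lipid handling (0.46, 25 of 28, percentile 100; *Gpnmb* 1.36, *Ctsk* 1.07, *Npc2* -0.31), tissue-resident macrophage genes (0.44, 8 of 11, percentile 99.9; *F13a1* 1.38 and *Pf4* 1.09 against *Ccl8* -1.41 and *Ccl12* -2), efferocytosis receptors and bridging proteins (0.43, 11 of 17, percentile 100; *Lrp1* and *Cd36* 0.82, *Axl* -0.70) and early-response and heat shock genes (0.40, 14 of 19, percentile 100; *Ier3* 1.31, *Dusp1* 1.09, *Ier2* -0.59). The lysosome list median went to 0.00 with cluster shares held equal and to -0.02 with finer cluster shares held equal. Among the main clusters averaged, it was lower in cluster 2 (-0.43, 21 of 25 lower) and higher in cluster 1 (0.16, 22 of 28 higher). In cluster 3 it was 0.15 (17 of 28 higher), with an interval of -0.20 to 0.36. Opposite differences thus average out, and the positive ones are smaller than the class median of 0.46. Cluster 0 (0.43, 24 of 26 higher) lies outside the class. With finer cluster shares held equal the medians were also smaller for repair (0.21), iron and haem handling (0.14), hypoxia (0.26) and efferocytosis (0.11). Those of tissue-resident and early-response genes were 0.37 and 0.33 there, and 0.22 and 0.15 with cluster shares held equal. *Ctsk* and *Cd36* also turned lower with finer cluster shares held equal (-0.0288 and -0.39). Early-response genes, which tissue dissociation induces, were higher in the Gata3KO library within cluster 1 (median 0.37) and lower within cluster 3 (-0.32). Their medians in clusters 0 (0.28, -0.01 to 0.69) and 2 (0.51, -0.01 to 0.84) had intervals that included 0.

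Lists of macrophage activation and metabolism showed smaller differences or went both ways. Alternative activation had a median of 0.07 (percentile 55.5; mean 0.41): 7 of 11 members were higher, led by *Chil3* and *Arg1*, and 4 were lower, with *Clec10a* at -1.86. Inflammatory mediators went both ways (median 0.14, mean -0.31, 12 of 24 higher, percentile 89.4), with *Cxcl1* at 1.79 and *Ccl7* at 1.30 against *Ccl5* and *Cxcl9* above. The IL-33 receptor pathway had a median of -0.18 (6 of 7 lower, percentile 5.36), with *Ucp2*, the mitochondrial carrier uncoupling protein 2, at 0.06 (-0.02 to 0.13) and *Nfkb1* at -0.51; with finer cluster shares held equal the list median was 0.16 and *Nfkb1* 0.0895. Nuclear genes of oxidative phosphorylation were higher by a small amount (median 0.15, 62 of 75 higher, none by 1.5 times, percentile 97.3; *Sdhd* 0.41, *Cycs* -0.49). The mitochondrial genome (0.14, percentile 84.2; *mt-Nd3* 0.58, *mt-Co1* -0.33) is limited by the filter on mitochondrial share, and over every deposited barcode *mt-Nd3* was -0.0945. The tricarboxylic acid cycle (0.08, percentile 65.5; *Idh1* 0.61, *Cs* -0.18) and fatty acid oxidation (0.06, percentile 63.0; *Hadh* 0.58, *Acsl1* -0.76) lay near the middle of random lists. Glycolysis had a median of 0.24 (percentile 98.4; *Eno1* 0.84, *Aldoa* 0.58, *Pfkfb4* -0.90), which turned to -0.06 with cluster shares held equal.

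Extracellular matrix genes went both ways (median 0.08, percentile 57.1; *Mmp8* 1.79, *Mmp12* -1.81), S phase (0.10, percentile 66.2) and G2 and M phase genes (0.08, percentile 60.1; *Mki67* 0.40, -0.02 to 0.82) had 5 and 4 measured members in a class from which the cycling cells had been left out (cycling macrophages were 3.23% of Wt and 11.1% of Gata3KO cells; with them included the G2 and M phase median was -0.60), and ribosomal protein genes were level (0.01, percentile 20.1; *Rpl3* 0.45). Of the lists for other cells the sample could hold, skeletal muscle genes had 3 measured members and a median of -1.52 (percentile 0.03; *Acta1* -1.61, *Mylpf* -1.57), and dendritic cell genes had 5 and a median of -1.50 (percentile 0.08; *Ccl22* -6.04, *Dpp4* -2.29). Neutrophil genes had 2 measured members (*Mmp8* above and *Csf3r* at -0.33), T and NK cell genes 2, and B cell genes 1 (*Ighm*, -1.30). Haemoglobin, fibroblast and endothelial, and mast cell, basophil and eosinophil genes had 0 measured members.

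**Figure D3:**
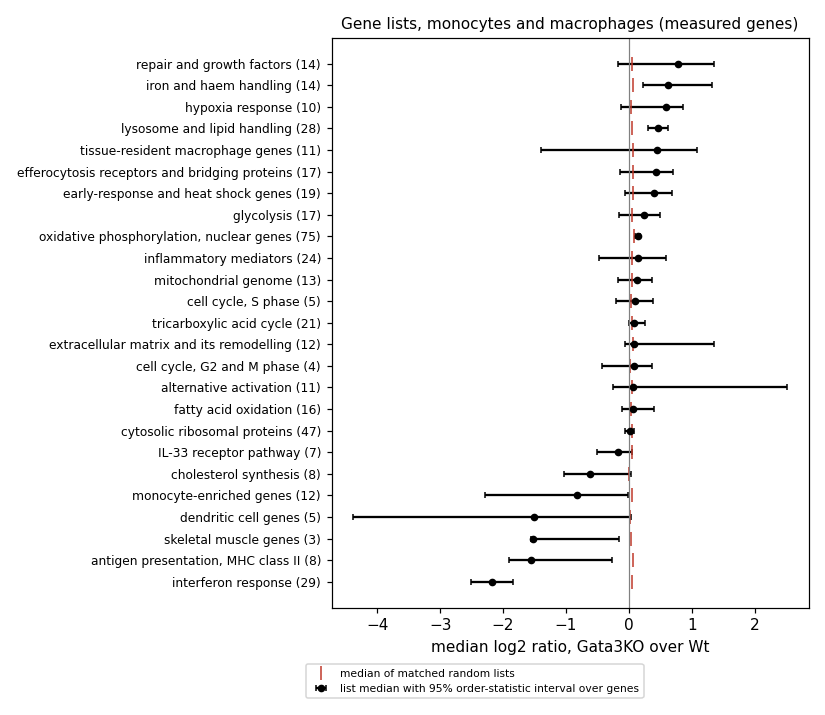
Median log2 ratio, Gata3KO over Wt (x axis), of each fixed gene list with at least 3 measured members (y axis, number in brackets) in monocytes and macrophages. Black bars are 95% order-statistic intervals over genes and red ticks the median of matched random lists; interferon response lies at -2.18 and repair and growth factors at 0.77.

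The lower interferon response was seen within clusters. Its list median was -1.62 in cluster 1 (29 of 29 members lower), -0.54 in cluster 2, -2.51 in cluster 3 and -1.32 in the unnamed cluster 0. MHC class II was lower in cluster 3 (-1.56, interval -2.02 to -0.54) and higher in cluster 2 (0.19, 0.13 to 0.46). Its medians in clusters 1 (-0.60, -1.13 to 0.06) and 0 (-0.57, -0.76 to 0.17) had intervals that included 0. Repair and growth factors were at 0.43 in cluster 1, -0.37 in cluster 2 and 0.17 in cluster 3, and iron and haem handling at 0.16, -0.08 and 0.64. A monocyte-like finer cluster of 35 Wt and 5 Gata3KO cells lies mostly in cluster 3, so its makeup differs between the libraries.

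Clusters 0 and 1 held at least 100 cells of each library. In cluster 1 *Chil3* had a log2 ratio of 3.73 (3.28 to 4.21; 24.9 CPM in Wt and 329 in Gata3KO), followed by *Gdpd3* (2.80), *Gdf15* (1.47) and *Cfp* (1.41). The macrophage elastase gene *Mmp12* (-2.93), *Gbp2* (-2.78), *Ly6a* (-2.41) and *Ifit2* (-2.24) were lowest. In cluster 0 *Mrc1* (2.58), *Spp1* (1.98), *Cxcl2* (1.77) and *Gdf15* (1.57) were highest and *Cxcl9* (-3.98), *Trim12a* (-3.37), *AW112010* (-3.04) and *Cxcl10* (-2.78) lowest. The makeup of cluster 0 also differs between the libraries. The finer clusters that lie mostly in it hold 176 Wt and 46 Gata3KO cells, 50 and 37, and 85 and 17 (conventional dendritic cell 2-like).

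**Figure D4:**
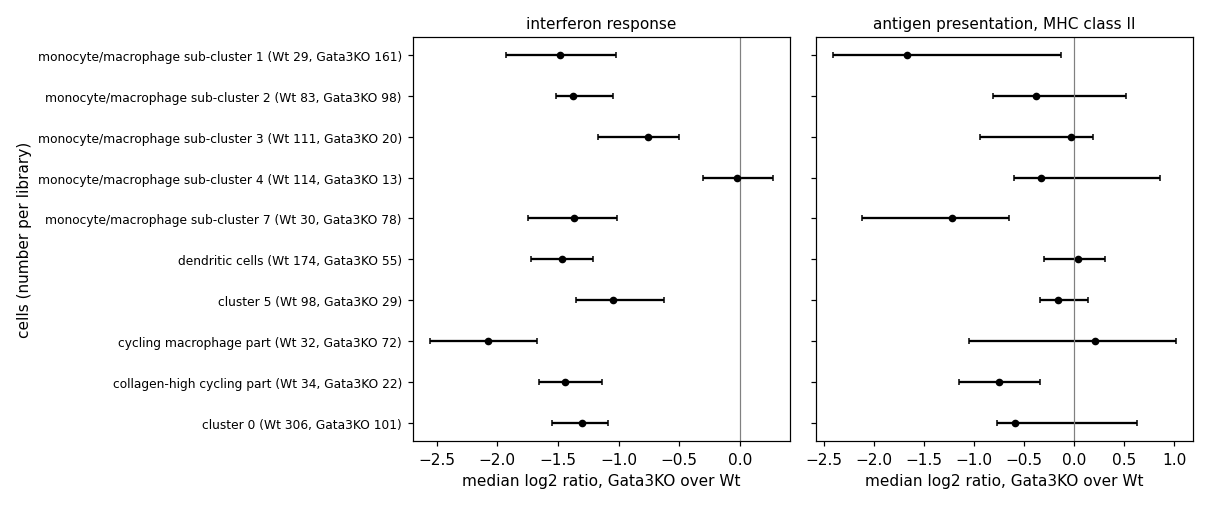
Median log2 ratio, Gata3KO over Wt (x axes), of the interferon response and the MHC class II list within groups of cells (y axis, cells per library; at least 10 in each) with 95% order-statistic intervals over genes. The interferon median lay below 0 in every group shown, at -1.47 in dendritic cells and -0.02 in sub-cluster 4, and sub-clusters come from the finer clustering.

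More cells carried a *Chil3*, *Gpnmb* or *Spp1* UMI in the Gata3KO library, and fewer an *H2-Aa* or *Ccr2* UMI. These shares are over the whole class and were not split by cluster. *Gpnmb* and *Spp1* are among the genes that lead cluster 1 (124 Wt and 198 Gata3KO cells). *Ccr2* is among those that lead cluster 2 (231 and 33), where *H2-Aa* was also highest within the class. Cluster makeup may therefore account for part of these differences. Every cell was thinned to 2000 UMIs, which left 393 Wt and 369 Gata3KO monocytes and macrophages (20 and 27 shallower cells were left out). *Chil3* was found in 5.09% of Wt (exact binomial interval 3.14 to 7.75%) and 30.1% of Gata3KO cells (25.4 to 35.0%), against 10.9% and 60.6% unthinned. In dendritic cells, which should lack it and had median depths of 7633 UMIs in Wt and 10591 in Gata3KO, it was found in 0 of 157 Wt cells and 0 of 48 Gata3KO cells (3 counts would be 1.91% and 6.25%). *Arg1* was found in 0.509% and 4.34% (2.66% and 10.1% unthinned; 0 dendritic cells in either library), with intervals that overlap when thinned to 1000 UMIs (0.06 to 1.77% and 0.90 to 4.03%).

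*Gpnmb* was found in 43.0% of Wt and 79.7% of Gata3KO cells (57.4% and 89.4% unthinned; 3.82% and 0% of dendritic cells), *Spp1* in 42.7% and 74.3% (61.5% and 91.2%; dendritic cells 5.73% and 8.33%), the insulin-like growth factor gene *Igf1* in 13.7% and 24.1% (33.7% and 60.9%; dendritic cells 1.27% and 6.25%) and *Gdf3* in 2.29% and 5.96% (4.6% and 12.1%; 0 dendritic cells), with overlapping intervals for *Gdf3*. *Il1b* was found in 9.67% and 20.1% (21.5% and 41.4%; dendritic cells 12.1% and 31.2%) and *Tnf* in 9.16% and 18.2% (21.1% and 43.9%; dendritic cells 5.73% and 14.6%), so the *Il1b* shares lay below those of dendritic cells. Thinned to 1000 UMIs, *Tnf* was found in 6.67% and 8.79% (4.44 to 9.55% and 6.16 to 12.1%), with overlapping intervals. *Cx3cr1* was found in 32.3% and 42.8% (60.5% and 73.2%; dendritic cells 15.3% and 8.33%), and in 21.7% and 26.6% thinned to 1000 UMIs, again with overlapping intervals. *H2-Aa* was found in 73.5% and 36.9% (91.0% and 60.4%; dendritic cells, which express it, 98.7% and 100%) and *Ccr2*, the monocyte chemokine receptor, in 50.4% and 28.7% (73.1% and 54.0%; dendritic cells, which express it, 37.6% and 58.3%).

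Shares of *Ucp2* (66.7% and 64.5%; unthinned 92.7% and 93.2%), *Mrc1* (17.0% and 17.6%; 39.0% and 54.5%; dendritic cells 4.46% and 4.17%) and *Ly6c2* (25.7% and 31.7%; 39.2% and 56.6%; dendritic cells 14.6% and 8.33%) had overlapping intervals after thinning. *Mki67* was found in 1.27% and 4.61% (10.4% and 16.2%; dendritic cells 2.55% and 0%) and *Top2a* in 0.763% and 2.44% (4.12% and 8.84%; dendritic cells 0.637% and 2.08%), close to background. *Gata3*, *Cd163*, *Retnla* and *Il1rl1*, the IL-33 receptor gene, were each found in at most 1 thinned cell per library, so no difference was detectable at this depth. *Nos2* was not analysed here.

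**Figure D5:**
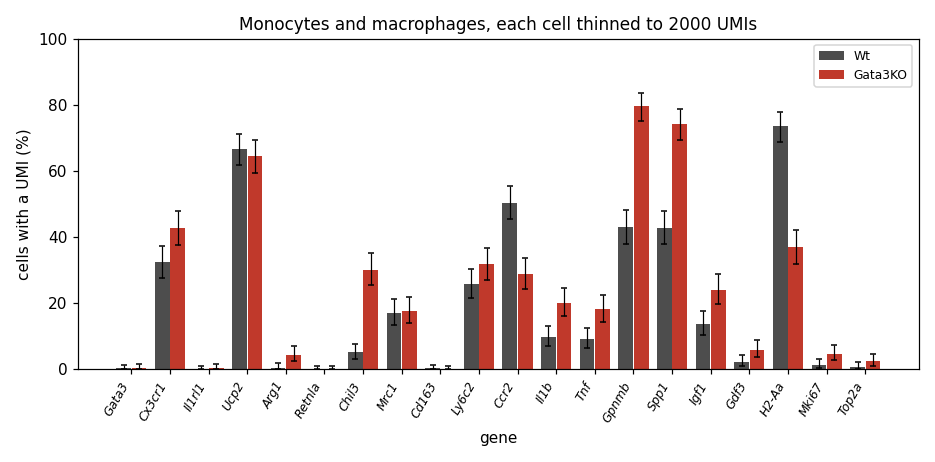
Share of monocytes and macrophages with at least 1 UMI of each panel gene (%, y axis; genes on the x axis) after every cell was thinned to 2000 UMIs, 393 Wt and 369 Gata3KO cells. Bars carry exact 95% binomial intervals; *Chil3* stands at 5.09% and 30.1% and *H2-Aa* at 73.5% and 36.9%.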

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

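Transcripts of cells outside the sort gate appear in cells outside the monocyte, macrophage and dendritic cell classes, and are given as values. In the muscle-transcript cluster of the Wt library *Acta1* stood at 2290 CPM, *Mylpf* at 2768 and *Myog*, a regulator of muscle differentiation, at 355, against 48.0, 51.1 and 9.60 in Wt monocytes and macrophages; 3 counts would be 13.2. The same cells had *C1qa* at 3071 CPM, against 2620 in monocytes and macrophages. In the collagen-rich cycling cells *Col1a1* stood at 2240 CPM in Wt and 2887 in Gata3KO, *Col3a1* at 1982 and 2036, and *Sparc* at 2346 and 1841, against at most 10.9 in monocytes and macrophages of either library. These cells also carried *C1qa* at 1073 and 1959 CPM.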

How the results depend on the processing

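No paired analysis was possible because each group has 1 library. The mitochondrial limit of 20%, the cycling macrophages, the UMI limit and the finer cluster shares were chosen after seeing the data. Over 21 alternatives and 162 results, 1692 of 2338 recomputed values stayed within their counting or order-statistic interval, 606 moved beyond it, 562 of them with the same sign, and 40 changed sign from a value whose interval lay clear of 0 or, for lists, whose percentile lay outside the central 95%. The interferon list stayed below 0 in every alternative. Depth and mitochondrial share differ between the libraries; the cause of the moves below was not tested unless stated.

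With every deposited barcode the share difference was -39.98 points for monocytes and macrophages in place of 19.2, and 49.04 for unnamed cells; 2281 of 3434 Gata3KO and 572 of 3290 Wt barcodes were unnamed. The interferon list was -1.76, oxidative phosphorylation 0.40, the lysosome list 0.76 and *Cx3cr1* 0.61. Signs changed for *Cd86* (0.0126), *Metrnl* (0.17), *Ndufa6* (0.0574), *Npc2* (0.0193), *Rpl24* (0.0417), *Rps24* (0.0973), *mt-Nd2* (-0.36) and *mt-Nd3* (-0.0945). With a mitochondrial limit of 20% the share differences were 9.52 and, for unnamed cells, 7.82 points. With the stricter filter *Cx3cr1* was 0.59, the dendritic cell difference -21.1 points and *Il7r* -0.29.

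At Leiden resolution 0.3 the share difference was 44.2 points, oxidative phosphorylation 0.0504, the lysosome list 0.17, glycolysis -0.0649, *Il7r* -0.34, *Msrb1* -0.13 and *Wdfy4* 0.0291. At 1.2 the share differences were 27.4 and, for dendritic cells, -14.7 points. With a class per cell from marker scores the dendritic cell difference was -13.4 points and *Cx3cr1* 0.34. With all kept cells *Cx3cr1* was 0.67, the lysosome list 0.66, *Grn* 0.10 and *Metrnl* 0.025. With every cell weighted alike oxidative phosphorylation was 0.25 and the lysosome list 0.66. With cells thinned oxidative phosphorylation was 0.19, *Eci1* -0.0246 and *Nasp* -0.16.

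With cluster shares held equal, which removes differences in cluster makeup by construction, the interferon list was -1.45, *Cx3cr1* 0.78, oxidative phosphorylation 0.0843, the lysosome list 0.00374, glycolysis -0.0608, *Arg1* -0.73, *Blvrb* -0.16, *Il7r* -0.85, *Msrb1* -0.0311 and *Nasp* -0.00412. With finer cluster shares held equal the interferon list was -1.15, *Cx3cr1* 1.08, oxidative phosphorylation 0.0881, iron and haem handling 0.14, the IL-33 receptor pathway 0.16, the lysosome list -0.0171 and monocyte-enriched genes 0.12. Signs changed there for *Arg1* (-0.63), *Blvrb* (-0.20), *Cd36* (-0.39), *Csf3r* (0.0303), *Ctsk* (-0.0288), *Hilpda* (-0.30), *Ighm* (0.14), *Il7r* (-0.75), *Jund* (0.0231), *Metrnl* (0.00226), *Nfkb1* (0.0895) and *Wdfy4* (0.0793). Median-of-ratios scaling, totals without mitochondrial and ribosomal protein genes, leaving out called doublets, the list filters and the larger added count moved no value beyond its interval.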

Other observations

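The difference in interferon response was also seen in cells outside the class of monocytes and macrophages. In dendritic cells 29 of 29 list members were lower in the Gata3KO library (median -1.47); the 2 libraries differ in which dendritic clusters they hold (cluster 6 has 71 Wt and 10 Gata3KO cells, cluster 8 has 5 and 16), and within cluster 5 alone the median was -1.05 with 27 of 29 lower. In cycling macrophages (32 Wt and 72 Gata3KO cells) the median was -2.08. The barcodes left out by the filters (2300 Wt and 2784 Gata3KO), which were not split by class and can hold macrophages, also had 29 of 29 members lower (median -1.60). MHC class II genes were lower in monocytes and macrophages as a class and in the collagen-rich cycling cells (median -0.75, 8 of 8 lower). Within the class their interval lay below 0 in finer clusters 1 (-1.67, -2.41 to -0.13) and 7 (-1.22, -2.13 to -0.65). It included 0 in finer clusters 2 (-0.38, -0.81 to 0.52), 3 (-0.04, -0.94 to 0.19), 4 (-0.33, -0.60 to 0.86) and 5 (-0.61, -1.34 to 3.48). MHC class II genes are among those that lead finer cluster 3, where a comparison of them has little to find. In dendritic cells (0.04), cycling macrophages (0.21, -1.05 to 1.02) and the monocyte-like finer cluster with 5 Gata3KO cells (0.50, -0.08 to 0.90) their intervals also included 0. The interferon median was -0.02 in a finer cluster that interferon genes define, where a comparison of these genes has little to find, and a resident-like finer cluster had too few Wt cells (5) to read it (0.23, interval -1.88 to 4.41). *Chil3* was higher in the Gata3KO library in each of the 7 finer clusters compared, from 1.79 to 7.11 on the log2 scale with 1 CPM added, although 2 of these clusters hold only 5 cells of 1 library.

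The tests of interferon genes by cluster makeup and depth, of MHC class II genes by cluster makeup and by abundant dendritic cell transcripts, and of the 12 higher genes by cluster makeup and in the barcodes left out were chosen after the results were seen. For the interferon response, cluster makeup was argued against as the whole cause. The list median was -1.15 (-1.31 to -0.97) with finer cluster shares held equal, which is smaller than -2.18, so makeup may account for part. With cells thinned the median was -2.10. Random thinning keeps each gene's expected share of a cell's UMIs, so this value cannot decide whether depth plays a part. A candidate explanation is that the loss of *Gata3* acts only inside cells that express *Cx3cr1*. The collagen-rich cycling cells were to serve as cells without it, and their list median was -1.44, which meets the bound set beforehand against this explanation. A check made afterwards showed that they carried *Cx3cr1* at 239 CPM in Wt, against 316 in the cycling macrophages, so that bound was wrong for these cells and the explanation stays open. A difference in interferon exposure between the animals or preparations, with 1 library per genotype, cannot be told apart from an effect of genotype.

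For MHC class II genes, RNA of dendritic cells in the Wt macrophages was argued against as the whole cause, by a test made after the bound set beforehand was not met. That bound was 3 times the highest share among 9 genes of dendritic cells, and the value was 1.39, because *Ccl22* reached 22.1% of its dendritic cell level. The MHC class II genes reached a median of 30.6%, which is 15.3 times the median of 2.00% reached by the 8 abundant genes of dendritic cells (10.5 times at their upper counting limits), and 6 of the 8 lay over 3 times below it at those limits. Cluster makeup stays open. Cluster 2, which gave 231 Wt and 33 Gata3KO cells, held *H2-Aa* at 5603 CPM over both libraries, against 1039 in cluster 1 and 1218 in cluster 3. With finer cluster shares held equal the MHC class II median was -0.58 with an interval of -1.02 to -0.12. This is smaller than the -1.56 of the class, so makeup may account for part.

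For the 12 genes highest in the Gata3KO library, the barcodes left out by the mitochondrial limit were not used to pick them. The median of the 12 in these barcodes was 1.27 (1.03 to 2.59) with 11 of 12 higher, so the difference was not confined to the kept cells. These barcodes were summed over every class, so cell makeup may add to the value. They cannot exclude the choice of cells by the limit within monocytes and macrophages. Over every deposited barcode the median was 1.92, which decides nothing, as these include the cells used for the pick. Cluster makeup stays open. With finer cluster shares held equal the median was 1.005 (0.81 to 1.43), with *Arg1* and *Hilpda* lower, but the genes were picked for their ratios in these cells. *Gdf15*, *Cxcl1*, *Hmox1*, *Arg1* and *Hilpda* are also among the genes that lead finer cluster 1, so holding its share equal conditions on them. In the finer cluster defined by interferon genes the median of the 12 was -0.11. An effect of genotype and a difference between the 2 preparations stay open too, as hypotheses.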
